A study of Lotus japonicus with 18 samples.

How the data were processed

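Shoots of Lotus japonicus WT and of 2 Ljmyb36 lines were sampled after 34 days of growth, 4 hours into the light period, from control plants and from plants whose NaCl was raised by 50 mM every 4 days to 100 mM, with about 2 days at the final level. RNA was extracted by a CTAB method and made into stranded poly(A) libraries with dUTP in the second strand, per the labels' protocols. The authors deposited a table of FPKM values per gene for 18 libraries, 3 for each of 6 groups. Reads were trimmed with fastp and counted with featureCounts 1.5.0-p3, and DESeq2 1.20.0 was used, per the submitters' processing notes. The aligner, the genome build and the strand setting of the counting are not given in the sources used here, so reads of overlapping, antisense and near-identical genes may be shared or split. Coordinates are those of the deposited table.

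The table held 33994 entries, of which 30584 were gene models and 3410 were assembled transcripts. A Swiss-Prot name was given for 22023 entries, a Pfam text alone for 3599, and no description for 8372. Gene names come from these descriptions, which are by similarity. Of the identifiers, 0 were found in the RefSeq gene table, so no names were taken from it. FPKM multiplied by gene length gave whole reads for 100% of nonzero values (tolerance 0.05 of a read). The recovered reads summed to between 42125949 and 101713201 per library, and the FPKM denominators followed median-of-ratios size factors of those reads. FPKM values are relative within a library. Labels call the replicates biological, without saying whether they came from separate pots or pools. No pair of libraries of 1 group agreed within sampling noise.

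The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with eBayes and a mean-variance trend, over all 18 libraries and 6 group means, which leaves 12 residual degrees of freedom. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 20433 in all. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Comparisons were salt against control in each genotype, each line against WT in each condition, the mean salt effect of the lines minus that of WT, and line 2 against line 1. A gene was counted for both lines when it passed in each in the same direction. Sharing of the WT libraries was simulated 100 times with unchanged groups. The tests, samples, alternatives and the rule for named genes were fixed before the data were examined.

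Gene lists, 35 in all, were patterns on the descriptions. After the protein names had been read, and before any comparison was computed, the patterns were edited: the Swiss-Prot name took precedence over the Pfam text, deoxychalcone synthases left the flavonoid core, NLR-like genes became a list apart from defence, chloroplast-encoded genes were taken by chromosome, and matches by accident of wording were removed. Lists were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison, and with fry. Members were also counted after adjustment over the list alone. Lists of other tissues were included. Of 4 leghemoglobin genes the highest FPKM was 0.257, so nodules were not detectable at this depth. In WT with salt the seed list had 0 genes called of 3, the flower and pollen list 2 up and 1 down of 33, the chloroplast-encoded list 0 of 102 and the cytosolic ribosomal protein list 1 up and 1 down of 204.

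Named genes followed a rule: every gene described as MYB36, the 8 highest and 8 lowest changes in the main comparisons among described genes with a mean FPKM of at least 5 in the higher group, and the 2 members of each list with the smallest adjusted p. From the genes the rule gave, the text names a part, and genes whose call was lost under several alternatives were passed over after their values were seen, so the named genes look steadier than the whole set, for which the closing section gives counts. Tests on defence and senescence genes picked for being higher in both lines were run and set aside after their results were seen, because the choice of genes made them void or they could not decide. A test of library scaling on the isoflavonoid list was also set aside as void, since taking off the median of all genes fixed its outcome. The iron genes other than ferritin-3 and the genes near 0 in a genotype were chosen after their values were seen.

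Alternatives tried were pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 5, median-of-ratios rescaling, quantile normalization, only the compared groups in the fit, the replicate number as a block, robust eBayes, array weights and leaving out each library of the compared groups. Chosen after seeing the data were limma voom on the recovered reads, scaling to the gene total, the library set as a term, and the 10 libraries of the lower set or the 8 of the upper set alone. The library sets were drawn from the first component of the deviations from the group means, and the 8 libraries of the upper set stand in columns 11 to 18 of the table. The procedure was tested on simulated data: for the salt effect in WT, limma recovered 61.6% of 99 genes changed 2-fold and 92.9% of 99 changed 4-fold, with 3 false calls among 20092 genes, and for the difference in salt effect 44.4% and 88.9%. Simulated reads were drawn independently for each gene, without the within-group component that the real libraries share. The changed genes were taken from those above a floor of mean reads. The false calls therefore do not cover such a shared component, and the recovery does not cover low genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.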

Results

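Gene expression was measured by RNA-seq of polyadenylated RNA from shoots of the legume Lotus japonicus. Wild-type (WT) plants and 2 Ljmyb36 mutant lines, called line 1 and line 2 here, were grown on nutrient solution without added NaCl (control) or with NaCl raised in steps of 50 mM to 100 mM (salt). Each of the 6 groups held 3 libraries labelled as biological replicates, which gave 18 libraries. The deposited FPKM values and gene lengths gave back whole reads for 100% of the nonzero values, within 0.05 of a read, and these summed to between 42125949 and 101713201 reads per library. In every pair of replicates the counts differed by more than sampling noise, with a median chi-square per gene of 2.11 in the closest pair. Of 33994 genes and assembled transcripts, 20433 passed the expression filter and were tested. Within groups the first principal component held 30.8% of the variance and parted 8 libraries (the upper set) from the other 10 (the lower set), with 1 or 2 of the 8 in every group. The lower set holds 1 control and 1 salt library of line 1, and the upper set 1 library of WT and of line 2 in each condition, so counts from 1 set alone rest on groups of 1 or 2. The cytosolic ribosomal protein genes lay higher in the 8 libraries, with a median deviation from the group mean of 0.16 on the log2 scale against -0.11 in the other 10. Over all tested genes, the changes computed within each set alone correlated between the sets at 0.18 for line 2 against line 1, at 0.52 and 0.58 for the salt effects in line 1 and line 2, and between 0.66 and 0.82 for the other comparisons.

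MYB36 is a MYB transcription factor known from Arabidopsis roots as a regulator of Casparian strip formation, and the series describes the mutants as knockouts of the Lotus gene. The table describes 5 genes as MYB36, the labels do not say which of them carries the mutation, and none of the 5 lost its signal in both lines. LotjaGi4g1v0091600 (chromosome 4, 12168340 to 12170131) had 6.36 ± 0.285 FPKM in WT control and 0.847 ± 0.131 in WT salt (SD, n = 3). It fell with salt in WT (log2 change -2.35, SE 0.22, limma adjusted p = 5.44e-07). In line 1 its level was 4.19 ± 0.768 FPKM in control and 3.90 ± 1.57 in salt, and in line 2 it was 4.02 ± 0.490 and 2.85 ± 0.631. In salt it was higher than in WT in line 1 and line 2 (log2 change 1.65 and 1.30, limma adjusted p = 3.66e-05 and 2.87e-04). In control neither line passed the threshold (limma adjusted p = 0.111 and 0.079). LotjaGi4g1v0298100 lay below the filter, with 0.0911 ± 0.0517 FPKM in WT control against 1.40 ± 0.735 in line 1 control and 0.771 ± 0.127 in line 2 control. Fitted without the filter, it was higher in both lines in control (log2 change 1.62 and 1.10, limma adjusted p = 6.00e-04 and 0.0091). In salt that fit gave log2 changes of 1.12 in line 1 and 0.57 in line 2 (limma adjusted p = 0.0066 and 0.123). LotjaGi1g1v0688400 had 1.37 ± 0.410 FPKM in WT control, 1.80 ± 0.498 in line 1 control and 2.79 ± 0.491 in line 2 control. LotjaGi3g1v0486500 had 0.600 ± 0.192, 0.923 ± 0.0986 and 1.02 ± 0.438. LotjaGi3g1v0167900, also below the filter, had 0.357 ± 0.174, 0.308 ± 0.164 and 0.303 ± 0.324. Transcript levels therefore did not check the genotype labels, since a mutated gene can still be transcribed.

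The salt effect in WT shoots included a loss of transcripts of isoflavonoid synthesis, the legume branch of flavonoid metabolism that makes defence compounds. Of 28 measured isoflavonoid and pterocarpan genes 0 rose and 17 fell, and the flavonoid core list had 1 up and 16 down of 27. Chalcone synthase LotjaGi2g1v0446700 (chromosome 2, 94134378 to 94136440), the first enzyme of flavonoid synthesis, went from 86.2 ± 27.4 FPKM in control to 3.52 ± 1.25 in salt (SD, n = 3). Of 90 auxin-response genes 30 rose and 6 fell. The comparison asks how 100 mM NaCl changed gene expression in WT plants.

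In the isoflavonoid list, NAD(P)H-dependent 6'-deoxychalcone synthase LotjaGi1g1v0006500 fell from 123 ± 35.03 to 5.53 ± 1.08 FPKM (log2 change -4.34, SE 0.20, limma adjusted p = 6.37e-10). Isoflavone 2'-hydroxylase LotjaGi4g1v0019000 fell from 173 ± 44.4 to 15.8 ± 4.02 FPKM (log2 change -3.41, SE 0.17, limma adjusted p = 1.16e-09). Adjusted over the list alone, 0 isoflavonoid genes rose and 19 fell, and 3 flavonoid core genes rose and 16 fell. The camera set test with a preset correlation gave an adjusted p = 5.14e-17 for the isoflavonoid list and 1.03e-09 for the flavonoid core, with limma, and both calls held at adjusted p = 0.041 and 0.019 with an estimated correlation. The series title names flavonoid and isoflavonoid genes as affected by the mutation, so these lists are not independent evidence of their direction. Phenylalanine ammonia-lyase LotjaGi1g1v0690200, which feeds phenylpropanoid metabolism, fell from 31.9 ± 6.41 to 3.80 ± 0.486 FPKM (log2 change -2.90, SE 0.13, limma adjusted p = 6.37e-10). The general phenylpropanoid list as a whole had 4 genes up and 5 down of 16, the same counts adjusted over the list alone. Many of these genes belong to families with near-identical copies, whose reads the counting could have split.

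Among WRKY, NAC and bZIP factors 3 rose and 40 fell of 111 (4 and 45 adjusted over the list alone), a call at a preset-correlation adjusted p = 1.63e-08 that was lost at adjusted p = 0.070 with an estimated correlation. WRKY53 LotjaGi1g1v0281800 went from 10.4 ± 2.48 to 0.0916 ± 0.0289 FPKM (log2 change -4.18, SE 0.25, limma adjusted p = 6.48e-09). The disease resistance (NLR-like) list had 1 up and 35 down of 145 (5 and 39 adjusted over the list alone), called at a preset adjusted p = 4.17e-06 and lost at adjusted p = 0.561 with an estimated correlation. Pathogenesis-related and defence genes had 7 up and 30 down of 107 (9 and 31 adjusted over the list alone), with a preset adjusted p = 0.039 and an adjusted p = 0.287 with an estimated correlation. In that list MLO-like protein 6 LotjaGi2g1v0102800 fell from 20.6 ± 3.94 to 0.840 ± 0.425 FPKM. The ethylene response factor gene ERF098 LotjaGi5g1v0180400 fell from 24.5 ± 5.74 to 0.636 ± 0.425 FPKM (log2 change -4.50, SE 0.25, limma adjusted p = 3.46e-09). The ethylene list had 7 up and 25 down of 108 (10 and 26 adjusted over the list alone) without a set call, at adjusted p = 0.135. The largest fall among described genes of at least 5 FPKM was in WAT1-related LotjaGi4g1v0030400, from 33.2 ± 15.2 to 0.475 ± 0.398 FPKM. SPX3 LotjaGi3g1v0206000, a sensor protein of phosphate status, fell from 79.5 ± 33.4 to 2.998 ± 2.26 FPKM. Phosphate transporter LotjaGi1g1v0709800 fell from 76.2 ± 11.5 to 17.1 ± 1.15. The clock gene REVEILLE 6 LotjaGi5g1v0296400 fell from 44.4 ± 6.65 to 1.61 ± 0.815 FPKM. LNK3 LotjaGi3g1v0315400, also named after a clock component, rose from 5.75 ± 0.644 to 47.04 ± 5.11, in libraries that were all harvested 4 hours into the light period.

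Auxin-response genes had 30 up and 6 down of 90 (33 and 7 adjusted over the list alone), with a preset adjusted p = 1.90e-05 that held at adjusted p = 0.019 with an estimated correlation. Auxin-induced protein 15A LotjaGi3g1v0478000_LC rose from 1.54 ± 0.799 to 18.8 ± 4.22 FPKM (log2 change 3.29, SE 0.27, limma adjusted p = 1.67e-07). Ammonium transporter LotjaGi5g1v0205600 rose from 4.07 ± 1.75 to 34.4 ± 14.2 FPKM. Nitrate transporter family gene NPF3.1 LotjaGi2g1v0278100 rose from 25.7 ± 2.58 to 78.6 ± 6.81, within a nitrate and phosphate transport list of 13 up and 21 down of 69 (15 and 22 adjusted over the list alone). Aquaporins had 7 up and 2 down of 29 (10 and 2 adjusted over the list alone). NIP2-1 LotjaGi1g1v0503000 rose from 5.29 ± 1.04 to 20.4 ± 2.16 FPKM, while the aquaporin list's preset adjusted p = 0.0050 became adjusted p = 0.44 with an estimated correlation. Photosystem and light-harvesting genes had 7 up and 0 down of 78 (4 and 0 adjusted over the list alone), called at 0.0035 and lost at adjusted p = 0.763 with an estimated correlation. Over all genes 3323 of 20433 were called. In lists tied to salt and drought, LEA proteins and dehydrins had 2 up and 3 down of 31, ABA genes 2 and 5 of 35, osmolyte synthesis 3 and 5 of 38, and sodium, potassium and chloride transport 14 and 7 of 79, none with a set call. Adjusted over the list alone these 4 lists had 2 and 3, 2 and 5, 4 and 6, and 17 and 7. The Casparian strip list, drawn by description, had 2 up and 3 down of 39 (1 and 3 adjusted over the list alone) and lignin genes 2 and 4 of 44 (2 and 4).

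In total 1298 genes rose and 2025 fell with salt in WT (limma, adjusted p under 0.05), of which 254 rose and 966 fell at least 2-fold on the log2(FPKM + 0.5) scale, which understates the change of low genes. With the 10 libraries of the lower set alone 2129 genes passed, and leaving out any 1 of the 6 WT libraries gave between 2612 and 2959.

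**Figure D1:**
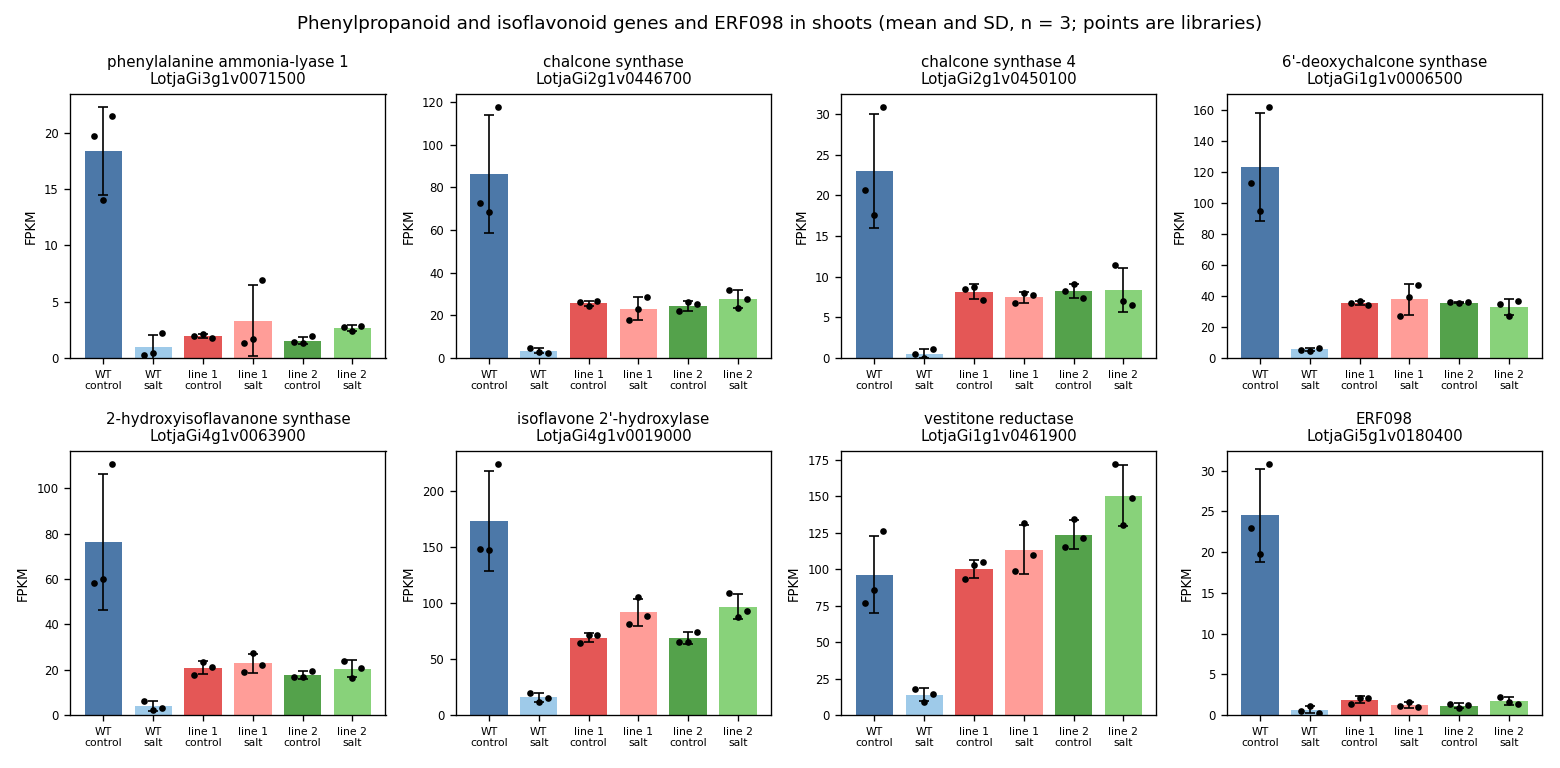
FPKM in the 6 groups for 7 genes of phenylpropanoid and isoflavonoid synthesis and for ERF098 (bars are means, error bars SD, points the 3 libraries). Chalcone synthase stood at 86.2 FPKM in WT control and 3.52 in WT salt, and between 23.2 and 27.7 in the 4 groups of the lines.

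In the mutant lines salt left the isoflavonoid genes near their control level. Of the 28 isoflavonoid genes 0 rose and 1 fell in line 1, and 2 rose and 0 fell in line 2, the same counts adjusted over the list alone. Chalcone synthase LotjaGi2g1v0446700 had 25.7 ± 1.17 FPKM in line 1 control and 23.2 ± 5.32 in line 1 salt, and 24.4 ± 2.22 and 27.7 ± 4.21 in line 2. Salt responses seen in WT that also appeared in a line included auxin-induced protein 15A LotjaGi3g1v0478000_LC, which rose in line 1 (log2 change 1.61, SE 0.27, limma adjusted p = 0.0010) and line 2 (log2 change 1.25, SE 0.27, limma adjusted p = 0.010). Inositol-3-phosphate synthase LotjaGi6g1v0085700, of osmolyte synthesis, rose by a log2 change of 0.70 in WT, 0.72 in line 1 and 0.73 in line 2.

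The general phenylpropanoid list had 4 up and 0 down of 16 in line 1 (4 and 0 adjusted over the list alone) and 2 up and 0 down in line 2 (6 and 0), with preset adjusted p = 0.0076 and 0.027 that became adjusted p = 0.239 and 0.412 with an estimated correlation. Auxin-response genes had 11 up and 3 down in line 1 (11 and 5 adjusted over the list alone) and 6 up and 3 down in line 2 (10 and 3), and WRKY, NAC and bZIP factors 4 up and 9 down (4 and 9) and 2 up and 8 down (2 and 8). In line 1 the preset test also called the WRKY, NAC and bZIP, antioxidant, clock, ribosomal protein and sodium, potassium and chloride lists, with adjusted p between 0.040 and 0.045, and none of these calls held at adjusted p of at least 0.636 with an estimated correlation. The ABA receptor PYL4 LotjaGi1g1v0074000 rose in WT (log2 change 1.36) and line 1 (2.24), and in line 2 its change was 0.17 (limma adjusted p = 0.627). Ferritin-3 LotjaGi3g1v0197600 (chromosome 3, 28953939 to 28957552), a chloroplast iron-storage protein, fell from 973 ± 36.5 to 134 ± 32.8 FPKM in line 1 and from 971 ± 98.4 to 125.5 ± 24.8 in line 2 (limma adjusted p = 2.54e-07 and 6.96e-07). It had 208 ± 37.9 and 167 ± 36.4 FPKM in WT control and salt. In all, 856 genes rose and 904 fell in line 1, and 866 rose and 904 fell in line 2. Of the genes called in WT, 493 also rose and 559 also fell in line 1, where independent lists would share 54.4 and 89.6. In line 2, 271 also rose and 282 also fell, where independent lists would share 55.0 and 89.6. Across genes, which are not independent replicates, the salt effects correlated at Pearson's r = 0.50 between WT and line 1, 0.30 between WT and line 2 and 0.58 between the lines. The count for the salt effect in myb36 line 1 moved by more than 1.5 times to 1084 and 1141 without control replicates 2 and 3 and to 1072 without salt replicate 1. For the salt effect in myb36 line 2 it moved to 833, 821 and 696 without control replicates 1, 2 and 3 and to 1065 without salt replicate 3. In line 1 the lower set alone gave 185 genes, from 1 library against 1, and the upper set 2260, from 2 against 2. In line 2 the lower set gave 300, from 2 against 2, and the upper set 94, from 1 against 1. Array weights raised the counts to 6104 in line 1 and 2846 in line 2, and the library set as a term raised that of line 2 to 3076. Within line 1 the weights ran from 0.230 to 8.20 between libraries, and the library set was drawn from these same data. Fitting only the compared groups, which leaves fewer samples, kept 704 of the 1760 calls in line 1 and 1198 of the 1770 in line 2. When scaled to the gene total, the share of rises moved from 48.6% to 38.8% in line 1 and from 48.9% to 23.7% in line 2.

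**Figure D2:**
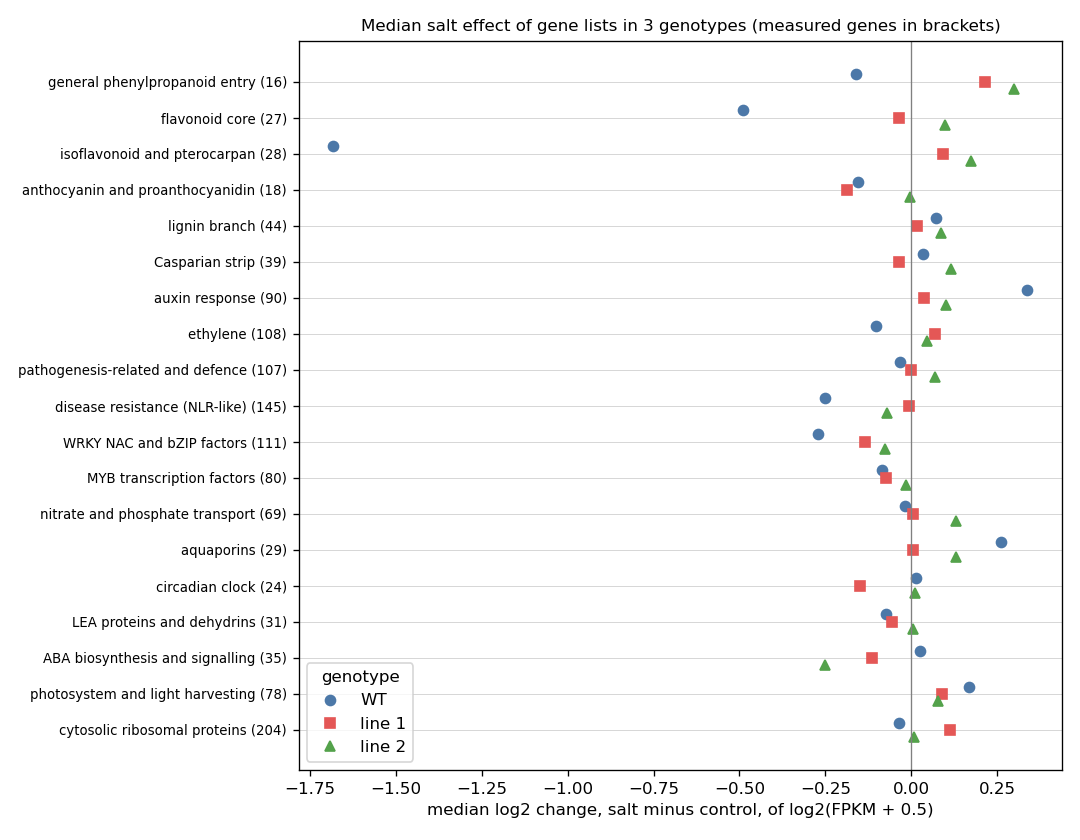
Median log2 change from control to salt over the measured genes of 19 lists, in WT (circles), line 1 (squares) and line 2 (triangles), with the number of genes in brackets. The isoflavonoid list stands apart, at -1.68 in WT, 0.09 in line 1 and 0.17 in line 2.

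Without salt, a sugar transporter gene, a senescence protease gene and several detoxification and defence genes were already higher in both mutant lines than in WT. The senescence-specific cysteine protease gene SAG12 LotjaGi6g1v0324100 (chromosome 6, 63966317 to 63968411) had 4.42 ± 2.62 FPKM in WT, 159 ± 18.97 in line 1 and 233 ± 22.9 in line 2 (SD, n = 3). SWEET10 LotjaGi1g1v0335600, a sugar exporter, had 1.52 ± 0.835 FPKM in WT, 83.3 ± 46.8 in line 1 and 122 ± 35.95 in line 2. Of the flavonoid core list 2 genes were higher and 11 lower in both lines, of 27 measured, a preset-correlation call that was lost at a larger adjusted p = 0.065 of the lines with an estimated correlation. The comparison asks how the lines, whose genotype transcript levels could not check, differed from WT in unstressed shoots.

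SWEET10 was higher by a log2 change of 5.24 in line 1 and 5.96 in line 2 (limma adjusted p = 3.01e-06 and 6.04e-07). SAG12 was higher by 5.13 and 5.69 (limma adjusted p = 2.28e-08 and 6.70e-09). Of 24 genes of chlorophyll breakdown and senescence 5 were higher and 0 lower in both lines (6 and 0 adjusted over the list alone), and 0 of 78 photosystem genes were called in both. Of 81 antioxidant enzymes 15 were higher and 2 lower (21 and 4 adjusted over the list alone). Of the neighbouring glutathione S-transferase genes, LotjaGi5g1v0258300 had 4.98 ± 3.06 FPKM in WT and 94.3 ± 8.81 and 104 ± 14.9 in the lines, and LotjaGi5g1v0258400 had 0.166 ± 0.236, 15.2 ± 2.69 and 18.95 ± 1.23. The defence list had 17 higher and 6 lower of 107 (19 and 8 adjusted over the list alone) without a set call. Its members included PR-4A LotjaGi1g1v0782200, at 15.6 ± 12.2 FPKM in WT against 191 ± 37.9 and 248 ± 46.2, and the beta-glucanase gene LotjaGi3g1v0535300, at 15.4 ± 2.95 against 110.1 ± 7.80 and 151 ± 6.60. WRKY, NAC and bZIP factors had 25 higher and 7 lower of 111 (29 and 9 adjusted over the list alone). WRKY40 LotjaGi1g1v0378000 was at 0.618 ± 0.330 FPKM in WT and 13.4 ± 4.49 and 15.2 ± 1.54 in the lines. Of 31 LEA proteins and dehydrins 9 were higher and 0 lower (10 and 0 adjusted over the list alone). Among them PCC13-62 LotjaGi6g1v0261400 was at 0.259 ± 0.163, 6.76 ± 1.70 and 10.96 ± 2.90 FPKM. Auxin-response genes had 20 higher and 2 lower of 90 (23 and 4 adjusted over the list alone) and MYB factors 6 and 0 of 80 (6 and 0). Ferritin-3 LotjaGi3g1v0197600 was higher by a log2 change of 2.24 in line 1 and 2.23 in line 2 (limma adjusted p = 1.08e-06 and 8.54e-07).

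In the Casparian strip list, drawn by description and holding CASP-like proteins, 4 of 39 were higher and 0 lower in both lines. Adjusted over the list alone the counts were 4 and 0, and there was no set call. Membership by description does not show a part in the root barrier that MYB36 is known to control. CASP-like protein 1D2 LotjaGi4g1v0346100 had 1.43 ± 0.567 FPKM in WT, 16.99 ± 4.17 in line 1 and 16.4 ± 2.17 in line 2. Lignin genes had 7 higher and 0 lower of 44 (7 and 1 adjusted over the list alone), and caffeic acid O-methyltransferase LotjaGi1g1v0005500 was at 3.83 ± 0.816, 16.6 ± 1.31 and 20.7 ± 2.26 FPKM. In the suberin and cutin list, with 10 higher and 2 lower of 103 (11 and 3 adjusted over the list alone), the lipase gene LotjaGi3g1v0397700 stood at 0.135 ± 0.0356 FPKM in WT and 9.81 ± 1.92 and 9.68 ± 0.899 in the lines. A pectinesterase gene, LotjaGi1g1v0763400, had 0.526 ± 0.248, 22.3 ± 7.10 and 20.3 ± 3.22 FPKM.

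Lower in both lines was ERF098 LotjaGi5g1v0180400, at 24.5 ± 5.74 FPKM in WT, 1.88 ± 0.414 in line 1 and 1.16 ± 0.273 in line 2. Phenylalanine ammonia-lyase LotjaGi3g1v0071500 was lower too, at 18.4 ± 3.93, 1.93 ± 0.176 and 1.56 ± 0.338. ERF098 was lower by a log2 change of -3.39 and -3.90 (limma adjusted p = 1.96e-07 and 2.97e-08). The chalcone synthase 4 genes LotjaGi2g1v0447000 and LotjaGi2g1v0449400 had 36.9 ± 11.4 and 17.3 ± 6.13 FPKM in WT, 7.19 ± 1.25 and 1.87 ± 0.414 in line 1 and 5.45 ± 0.669 and 1.78 ± 0.313 in line 2. Phenylpropanoid entry genes had 1 higher and 5 lower of 16 (1 and 5 adjusted over the list alone), and the flavonoid core counts were 2 and 11 adjusted over the list alone. The isoflavonoid list split, with 6 higher and 9 lower of 28 (7 and 10 adjusted over the list alone). The 2-hydroxyisoflavanone dehydratase gene LotjaGi1g1v0018600 was at 0.930 ± 0.685 FPKM in WT and 6.90 ± 1.16 and 7.02 ± 0.212 in the lines. Deoxychalcone synthase LotjaGi1g1v0006500 was at 123 ± 35.03, 35.8 ± 1.35 and 35.8 ± 0.486. As the series title names these pathways, their lists are not independent evidence here either. Also lower were the receptor kinase gene LotjaGi1g1v0358400 (18.1 ± 3.83, 2.27 ± 0.324 and 2.59 ± 0.215 FPKM), beta-glucosidase 12 LotjaGi3g1v0497400 (15.9 ± 6.29, 2.58 ± 0.379 and 2.54 ± 0.469) and the VQ motif gene LotjaGi4g1v0359500 (18.5 ± 2.000, 2.85 ± 0.566 and 2.13 ± 0.116).

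Line 1 had 1505 genes higher and 881 lower than WT in control and line 2 had 1476 and 1094, and 1123 were higher and 633 lower in both (limma, adjusted p under 0.05). Independent lists would share 108.7 and 47.2 genes. The lines share the WT libraries, and in 100 simulations of unchanged groups 0 genes were called in both. Unchanged groups give almost no calls in either line, so this count cannot show how much overlap comes from the shared libraries. The simulated correlation of the changes averaged 0.498 and reached 0.910, against an observed 0.907, so the correlation lay within what unchanged groups gave. The simulated covariance averaged 0.0271 and reached 0.103, against 0.213. With 3 WT libraries both parts of a split could not keep 2, so the controls were not split and part of the excess may come from them. The preset-correlation set test called 8 lists in both lines, and with an estimated correlation 0 were called. The larger adjusted p of the lines with an estimated correlation was 0.065 for the flavonoid core, 0.136 for phenylpropanoid entry, 0.065 for senescence and 0.079 for auxin. It was 0.164 for MYB factors, 0.172 for LEA proteins, 0.175 for antioxidant enzymes and 0.193 for WRKY, NAC and bZIP factors. The count for both lines against WT in control dropped to 1140 without WT control replicate 3 and to 400 with the 10 libraries of the lower set alone, where line 1 control is 1 library, and rose to 5101 with array weights. For line 1 against WT in control the count was 1475 without that WT library and 1416 without the line's replicate 2, and 7988 with array weights. For line 2 against WT in control it was 1685 without that WT library, 1687 and 1708 without the line's replicates 2 and 3, and 6101 with array weights. With quantile normalization 52.1% of the calls in line 1 were higher than WT, against 63.1%, and scaled to the gene total 73.9% of those in line 2 were, against 57.4%.

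**Figure D3:**
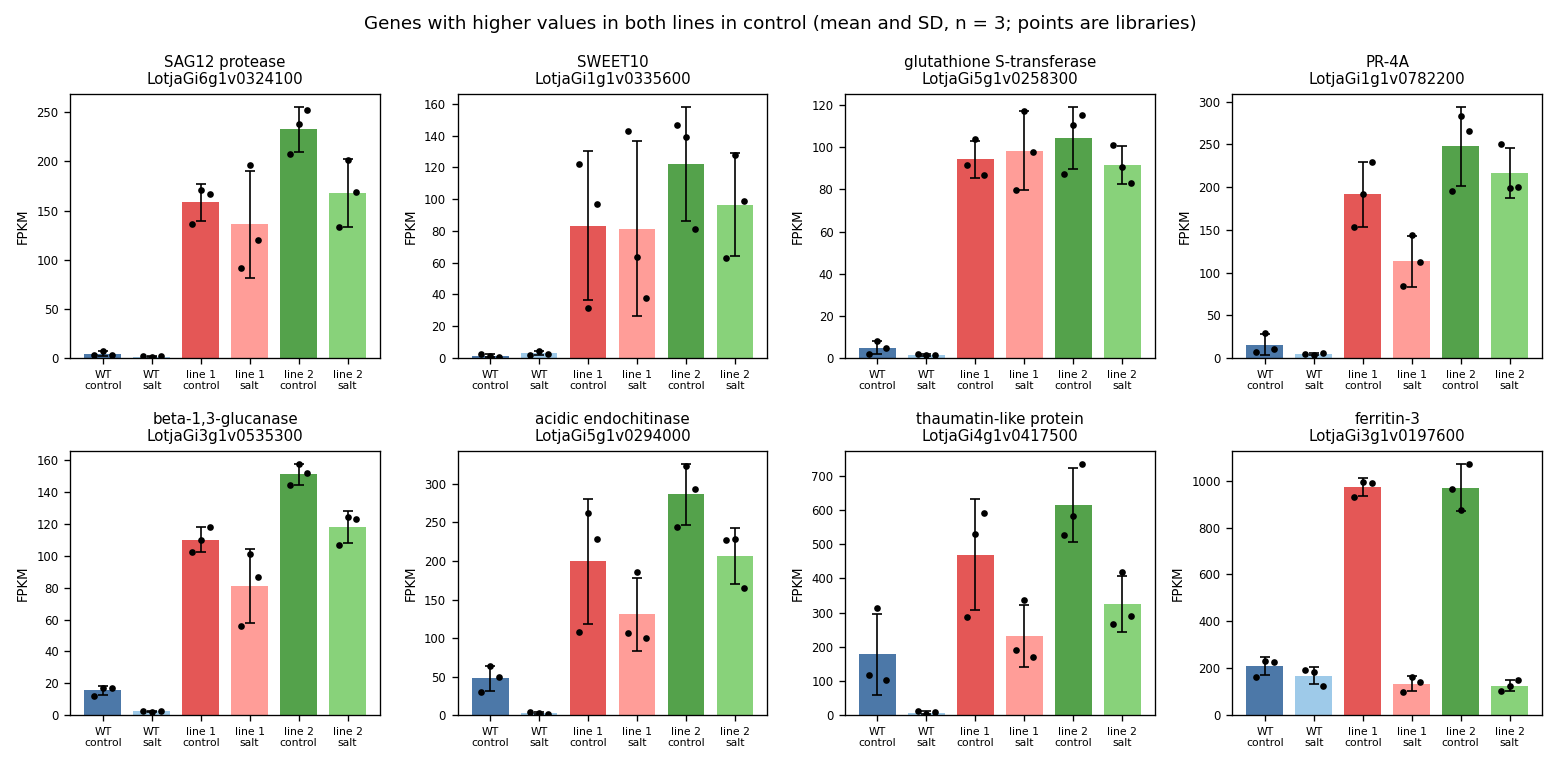
FPKM in the 6 groups for 8 genes that were higher in both lines in control (bars are means, error bars SD, points the 3 libraries). SAG12 stood at 4.42 FPKM in WT control against 159 and 233 in the lines, and ferritin-3 at 973 and 971 in the lines in control against 134 and 125.5 in salt.

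Under salt, 21 of 28 isoflavonoid genes were higher and 0 lower in both lines than in WT, and of 111 WRKY, NAC and bZIP factors 51 were higher and 0 lower. As sets both lists were called with a preset correlation, and both calls were lost at a larger adjusted p = 0.059 of the lines with an estimated correlation. The beta-glucanase gene LotjaGi3g1v0535300 had 2.44 ± 0.271 FPKM in WT, 81.1 ± 23.1 in line 1 and 118 ± 9.98 in line 2 (SD, n = 3). Acidic endochitinase LotjaGi5g1v0294000, an enzyme that cleaves chitin, had 2.77 ± 0.852, 131 ± 47.3 and 207 ± 36.4 FPKM. The comparison asks how the lines differed from WT after the same salt treatment.

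Endochitinase was higher in line 1 and line 2 (limma adjusted p = 8.08e-09 and 1.77e-09). The beta-glucanase gene was higher by 4.76 and 5.34 (2.40e-11 and 1.53e-11, limma adjusted p). The defence list had 29 higher and 2 lower of 107 (29 and 4 adjusted over the list alone), and the NLR-like list 23 and 2 of 145 (25 and 3). A thaumatin-like protein gene, LotjaGi4g1v0417500, had 7.29 ± 4.15 FPKM in WT, 232 ± 91.8 in line 1 and 325 ± 82.6 in line 2. The lipid-transfer protein gene LotjaGi6g1v0042700 had 2.53 ± 1.63, 75.9 ± 24.2 and 114 ± 7.78. The receptor kinase gene SERK2 LotjaGi5g1v0283300 had 0.103 ± 0.136, 19.8 ± 4.22 and 21.4 ± 3.73. In the isoflavonoid list (24 and 0 adjusted over the list alone) vestitone reductase LotjaGi1g1v0461900, which acts late in pterocarpan synthesis, had 13.9 ± 4.48 FPKM in WT, 113 ± 16.7 in line 1 and 151 ± 21.1 in line 2. The isoflavone 7-O-methyltransferase gene LotjaGi1g1v0513400 had 1.33 ± 0.644, 21.7 ± 2.35 and 29.6 ± 5.67. The flavonoid core had 12 higher and 2 lower of 27 (13 and 2 adjusted over the list alone) and phenylpropanoid entry 6 and 0 of 16 (8 and 0), and the caution about lists named in the series title holds here too. WRKY6 LotjaGi6g1v0292300 had 3.40 ± 0.156, 24.8 ± 6.86 and 26.96 ± 2.19 FPKM, in a list with 58 higher and 1 lower adjusted over the list alone. MYB123 LotjaGi3g1v0398400 had 1.54 ± 0.167, 11.7 ± 1.05 and 14.1 ± 1.91, in a MYB list with 16 higher and 0 lower of 80 (19 and 0). Nitrate and phosphate transport had 18 higher and 2 lower of 69 (18 and 2), antioxidant enzymes 22 and 1 of 81 (22 and 1), and ethylene genes 23 and 1 of 108 (25 and 1). LEA proteins and dehydrins had 8 and 0 of 31 (8 and 0), senescence genes 8 and 4 of 24 (9 and 4) and histones and cell cycle genes 6 and 14 of 140 (7 and 15), with the brackets adjusted over the list alone. Caffeoyl-CoA O-methyltransferase LotjaGi2g1v0230500, in a lignin list of 10 higher and 1 lower of 44 (10 and 1 adjusted over the list alone), had 6.44 ± 3.36, 101.2 ± 16.3 and 117 ± 23.1 FPKM.

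Lower in both lines under salt was 2-isopropylmalate synthase LotjaGi1g1v0613100, an enzyme of leucine synthesis, with 39.4 ± 2.32 FPKM in WT, 16.5 ± 1.92 in line 1 and 13.9 ± 1.27 in line 2. Phosphoethanolamine N-methyltransferase LotjaGi2g1v0196500, an enzyme of phosphocholine synthesis, had 48.4 ± 3.22, 19.6 ± 3.43 and 16.1 ± 0.496. The cytochrome P450 genes LotjaGi1g1v0018100_LC and LotjaGi3g1v0093500_LC had 7.49 ± 1.74 and 53.8 ± 3.89 FPKM in WT, 2.48 ± 1.16 and 20.7 ± 1.42 in line 1, and 0.653 ± 0.332 and 16.2 ± 1.87 in line 2. The light-signalling gene FAR1 LotjaGi6g1v0185700 had 8.59 ± 1.78, 1.91 ± 0.549 and 1.41 ± 0.654 FPKM.

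Line 1 had 2293 genes higher and 974 lower than WT in salt and line 2 had 3042 and 2083, and 1929 were higher and 673 lower in both, where independent lists would share 341 and 99.3. In 100 simulations of unchanged groups against the shared WT libraries 0 genes were called in both, and the covariance averaged 0.0282 and reached 0.112, against an observed 0.312. The simulated correlation averaged 0.484 and reached 0.884, above the observed 0.875. Of the 2025 genes that fell with salt in WT, 1047 (51.7%) were higher in both lines in salt, against 191 for independent lists. Both comparisons use the WT salt libraries, and in the simulations of unchanged groups 0 genes did so. Unchanged groups give almost no calls in any comparison, so neither simulated count can show how much overlap comes from the shared libraries. In both conditions 724 genes were higher in both lines (106 for independent lists) and 119 lower (20.8). The preset-correlation set test called 11 lists in both lines, and 0 were called with an estimated correlation. The larger adjusted p of the lines was then 0.059 for isoflavonoid genes, 0.059 for WRKY, NAC and bZIP factors, 0.078 for ethylene and 0.090 for MYB factors. It was 0.112 for cell cycle, 0.156 for the flavonoid core, 0.156 for defence, 0.156 for nitrate and phosphate transport, 0.159 for senescence, 0.172 for LEA proteins and 0.189 for antioxidant enzymes. The count for both lines against WT in salt was 1303 with the 10 libraries of the lower set alone, where line 1 salt is 1 library, and 1573 with only the compared groups fitted. For line 1 against WT in salt array weights raised the count to 6147. With quantile normalization the share of calls higher than WT moved from 70.2% to 49.8% in line 1 and from 59.4% to 44.8% in line 2.

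The salt effect on isoflavonoid genes differed between the lines and WT, with 17 of 28 genes that fell in WT against 1 in line 1 and 0 in line 2. Of the 28 isoflavonoid genes 17 had a salt effect that was higher in the lines and 0 a lower one, and the flavonoid core had 13 and 0 of 27. For 2-hydroxyisoflavanone synthase LotjaGi4g1v0063900 (chromosome 4, 7995539 to 7997935), the enzyme at the entry of the isoflavonoid branch, WT had 76.4 ± 29.9 FPKM in control and 3.90 ± 2.17 in salt, line 1 20.9 ± 2.98 and 22.9 ± 4.27, and line 2 17.7 ± 1.70 and 20.5 ± 3.78 (SD, n = 3). Auxin-response genes went the other way, with 2 higher and 12 lower of 90. The comparison takes the mean salt effect of both lines minus that of WT.

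The salt effects on 2-hydroxyisoflavanone synthase differed by 4.33 (SE 0.35, limma adjusted p = 6.44e-07). They differed on chalcone synthase LotjaGi2g1v0446700 by 4.43 (SE 0.27, limma adjusted p = 5.87e-08) and on chalcone synthase 4 LotjaGi2g1v0450100 by 4.54 (SE 0.38, limma adjusted p = 1.02e-06). The phenylpropanoid list had 7 higher and 0 lower of 16 (7 and 0 adjusted over the list alone), and the isoflavonoid list 18 and 0 and the flavonoid core 15 and 2 adjusted over the list alone. Their preset adjusted p = 2.88e-05, 1.54e-21 and 5.66e-11 held at adjusted p = 0.018, 0.018 and 0.013 with an estimated correlation. A second deoxychalcone synthase gene, LotjaGi4g1v0144700, had 9.13 ± 4.59 and 0.361 ± 0.261 FPKM in WT and 2.30 ± 0.465 and 3.61 ± 0.101 in line 1. The defence list had 24 higher and 0 lower of 107 (26 and 1 adjusted over the list alone), with a preset adjusted p = 9.14e-04 that held at adjusted p = 0.047 with an estimated correlation. The NLR-like list had 21 and 0 of 145 (28 and 1 adjusted over the list alone), WRKY, NAC and bZIP factors 28 and 0 of 111 (35 and 3) and ethylene genes 16 and 4 of 108 (21 and 4). Their preset adjusted p = 1.64e-04, 1.61e-05 and 0.013 became adjusted p = 0.613, 0.131 and 0.12 with an estimated correlation. In the NLR-like list RPV1 LotjaGi4g1v0059300 had 3.75 ± 1.02 and 0.119 ± 0.139 FPKM in WT control and salt against 3.34 ± 0.251 and 2.25 ± 0.566 in line 1. ERF098 LotjaGi5g1v0180400 differed by 4.48, from the fall in WT, while the lines stayed between 1.16 and 1.88 FPKM in both conditions. The fatty acid elongation gene LotjaGi3g1v0510500 (3-ketoacyl-CoA synthase 11) had 36.3 ± 10.1 and 5.51 ± 1.38 FPKM in WT and 13.8 ± 0.724 and 14.4 ± 4.40 in line 2.

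Auxin-response genes had 3 higher and 19 lower adjusted over the list alone, with a preset adjusted p = 1.64e-04 that held at adjusted p = 0.020 with an estimated correlation. ARG7 LotjaGi3g1v0516400 had 1.94 ± 0.706 and 10.5 ± 2.65 FPKM in WT, 6.18 ± 1.77 and 5.72 ± 0.765 in line 1 and 3.61 ± 1.05 and 5.67 ± 1.79 in line 2. Ferritin-3 LotjaGi3g1v0197600 had the most negative difference among the genes named here, -2.60 (SE 0.24, limma adjusted p = 2.75e-06). The Casparian strip list had 4 higher and 0 lower of 39 (4 and 1 adjusted over the list alone), without a set call.

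In total 1203 genes had a higher and 464 a lower salt effect in the lines than in WT (limma, adjusted p under 0.05), and leaving out any 1 library gave between 1202 and 1735. Tested apart, the difference from WT held for 738 genes higher and 135 lower in line 1 and for 1199 and 560 in line 2, and the salt effects of the lines differed from each other for 63 genes. With the 10 libraries of the lower set alone 946 genes passed for both lines together, and with the 8 of the upper set 507, while array weights gave 2996 for the difference in salt effect between the lines and WT. The isoflavonoid list had a median difference of 1.32 within the 8 libraries of the upper set and 2.15 within the other 10.

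**Figure D4:**
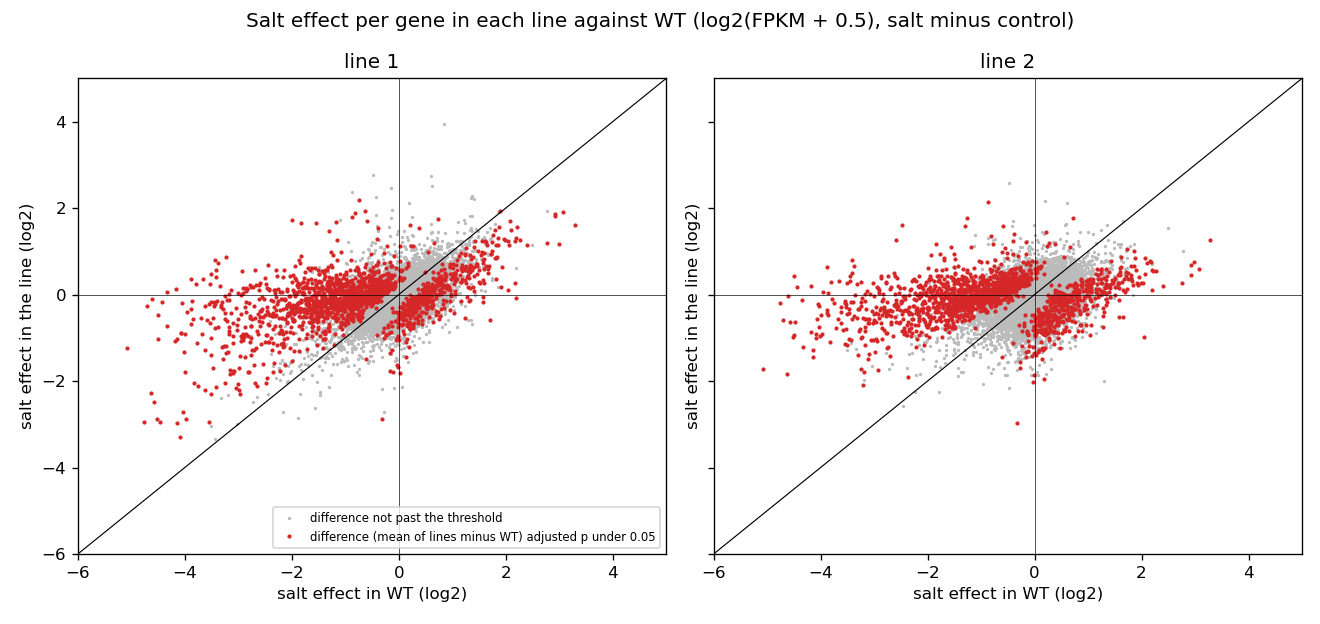
Log2 change from control to salt of each tested gene in line 1 (left) and line 2 (right) against that in WT, with the 1667 genes whose difference passed the threshold in red and the diagonal of equal effects. Many genes that fell in WT lie near 0 in the lines.

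Averaged over control and salt, 53 genes were higher and 72 lower in line 2 than in line 1 (limma, adjusted p under 0.05; 1932 at an unadjusted p under 0.05), and no fixed list had more than 2 genes called in either direction. The flavonoid core had 0 higher and 1 lower of 27 and the isoflavonoid list 0 called of 28. The photosystem list had a preset adjusted p = 4.34e-04 with a median of -0.10, which became adjusted p = 0.83 with an estimated correlation, and the lignin list went from 0.032 to adjusted p = 0.324 with an estimated correlation. In each condition the upper library set holds 2 libraries of line 1 and 1 of line 2. Differences between the library sets therefore enter this comparison, and the photosystem median may carry part of them. The count of 125 moved to 83 and 74 without line 1 control replicates 1 and 2 and to 77 and 79 without line 2 control replicates 1 and 2, and was 68 with the 10 libraries of the lower set alone and 77 with the 8 of the upper set. For line 2 against line 1 it rose to 250 with the library set as a term and to 915 with array weights, so the number of genes that differ between the lines is not settled. The share of calls higher in line 2 was 42.4%, and it moved to 51.4% with quantile normalization and 61.9% when scaled to the gene total.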

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

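The test of each named gene's difference was planned, while the counts of other splits of the samples, the library set and the check on genes with a protein name of their own were tests chosen after the result was seen. The salt effect differed between the lines and WT for 1667 genes and between line 2 and line 1 for 63 genes (limma, adjusted p under 0.05), which drew attention to each gene below, as a tested difference between genotypes. All values are log2 differences, the mean salt effect of the lines minus that of WT.

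Flavonoid and isoflavonoid genes had positive differences: 4.54, 4.43, 3.99 and 3.38 for the chalcone synthase genes LotjaGi2g1v0450100, LotjaGi2g1v0446700, LotjaGi2g1v0449400 and LotjaGi2g1v0447000, 4.30 and 4.11 for the deoxychalcone synthase genes LotjaGi1g1v0006500 and LotjaGi4g1v0144700, 4.33 for 2-hydroxyisoflavanone synthase LotjaGi4g1v0063900 and 3.86 for isoflavone 2'-hydroxylase LotjaGi4g1v0019000. Vestitone reductase LotjaGi1g1v0461900 differed by 2.99, isoflavone 7-O-methyltransferase LotjaGi1g1v0513400 by 2.19 and 2-hydroxyisoflavanone dehydratase LotjaGi1g1v0018600 by 1.58. The phenylalanine ammonia-lyase genes LotjaGi3g1v0071500 and LotjaGi1g1v0690200 differed by 4.37 and 2.98, and the methyltransferase genes LotjaGi2g1v0230500 and LotjaGi1g1v0005500 by 3.17 and 1.30.

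Regulators with positive differences were ERF098 LotjaGi5g1v0180400 (4.48), WRKY53 LotjaGi1g1v0281800 (3.22), WRKY6 LotjaGi6g1v0292300 (2.59), MYB123 LotjaGi3g1v0398400 (2.31), REVEILLE 6 LotjaGi5g1v0296400 (2.67), the VQ motif gene LotjaGi4g1v0359500 (3.29) and the MYB36-described gene LotjaGi4g1v0091600 (2.06). Defence and signalling genes were thaumatin-like LotjaGi4g1v0417500 (3.53), endochitinase LotjaGi5g1v0294000 (3.33), MLO-like LotjaGi2g1v0102800 (3.07), RPV1 LotjaGi4g1v0059300 (2.27), beta-glucanase LotjaGi3g1v0535300 (2.01), lipid-transfer protein LotjaGi6g1v0042700 (2.27), SERK2 LotjaGi5g1v0283300 (1.32) and receptor kinase LotjaGi1g1v0358400 (2.56). Other positive differences were 4.28 for beta-glucosidase 12 LotjaGi3g1v0497400, 3.61 for WAT1-related LotjaGi4g1v0030400, 2.73 for LotjaGi3g1v0510500, 2.57 for SPX3 LotjaGi3g1v0206000, 1.80 for phosphate transporter LotjaGi1g1v0709800 and 0.57 for oligopeptide transporter 3 LotjaGi4g1v0006400.

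Negative differences were -2.60 for ferritin-3 LotjaGi3g1v0197600, -2.02 and -1.69 for the cytochrome P450 genes LotjaGi1g1v0018100_LC and LotjaGi3g1v0093500_LC, -1.94 for ARG7 LotjaGi3g1v0516400, -1.86 for auxin-induced protein LotjaGi3g1v0478000_LC, -1.77 for ammonium transporter LotjaGi5g1v0205600, -1.67 for LNK3 LotjaGi3g1v0315400, -1.50 for 2-isopropylmalate synthase LotjaGi1g1v0613100, -1.32 for FAR1 LotjaGi6g1v0185700, -1.07 for lipase LotjaGi3g1v0397700, -1.03 for NPF3.1 LotjaGi2g1v0278100 and -0.71 for aquaporin LotjaGi1g1v0503000.

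The isoflavonoid pattern, a fall of many genes in WT with salt and of few in the lines, was weighed against technical explanations. Of the 28 genes 9 were already lower and 6 higher in both lines in control, so part of the difference lies in control levels. Over all genes, 294 of the 2025 that fell with salt in WT were lower in both lines in control (62.7 for independent lists). Another 268 were higher (111 for independent lists). These comparisons share the WT control libraries. The within-group library set as its source is argued against by the list's median difference, which was still 1.32 in the set where it was smaller. For reads shared between paralogs, the 5 isoflavonoid genes that alone carry their protein name were looked at, and 4 of them passed with a higher value in the lines. Names are by similarity and many entries have none, so such a gene can still have a near-identical copy. The count therefore cannot decide on shared reads. A biological difference between the genotypes may explain the pattern, as a hypothesis, though undetected differences in the growth or timing of the WT salt plants stay open.

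Other splits of the samples were counted for each comparison. With 3 against 3 there are 10 splits, too few for a share under 0.05: in each, 1 of the 10 splits, the real one, gave as many genes. The real counts and highest others were 3323 and 1 for salt in WT, 1760 and 0 for salt in line 1, 1770 and 0 for salt in line 2, 2386 and 0 for line 1 and 2570 and 1 for line 2 against WT in control, and 3267 and 2 for line 1 and 5125 and 1 for line 2 against WT in salt. Of 100 splits drawn, 1, the real one, reached the count for both lines in control (1756, highest other 17), for the difference in salt effect (1667, highest other 79) and for line 2 against line 1 (125, highest other 32). Other splits mix libraries of different groups, so real differences enter the spread and lower their counts. The splits therefore cannot exclude any source that goes with the real groups. For both lines in salt 1 of 100 splits reached 2602, and the highest other, 2597, came from a split that kept the WT libraries together and exchanged libraries between the lines. Among the 98 splits with another WT group the highest was 12, so that count rests on the parting of WT from the lines, not on which line a library came from.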

How the results depend on the processing

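The voom fit, the scaling to the gene total, the library set as a term and the fits to the 10 libraries of the lower set and to the 8 of the upper set were tests chosen after the result was seen, and the others were planned. Counts of genes past the threshold stayed within 1.5 times under both pseudocounts, no filter, median-of-ratios rescaling, quantile normalization, robust eBayes and voom. The FPKM denominators already followed median-of-ratios size factors, so that rescaling could change little and is a weak check. Array weights raised the count to 6104 for the salt effect in myb36 line 1 and 2846 for the salt effect in myb36 line 2. They gave 7988 for line 1 against WT in control, 6101 for line 2 against WT in control, 6147 for line 1 against WT in salt and 5101 for both lines against WT in control. They gave 2996 for the difference in salt effect between the lines and WT and 915 for line 2 against line 1, and the cause was not tested. The weights ran from 0.230 for line 1 salt replicate 3 to 8.20 for line 1 control replicate 3. The weighted fits therefore lean on few libraries of line 1. With fewer samples, the 10 libraries of the lower set gave 2129, 185 and 300 genes for the salt effect in WT, line 1 and line 2. They gave 478, 1305 and 400 for line 1, line 2 and both lines in control, and 1793 for line 1, 2893 for line 2 against WT in salt and 1303 for both lines against WT in salt. They gave 946 for the difference and 68 between the lines. In these 10, line 1 has 1 library per condition. The 8 libraries of the upper set, with 1 library per condition of WT and of line 2, gave 2367, 2260 and 94 for salt in WT, line 1 and line 2, 1213 and 788 for lines 1 and 2 in control, 2100 and 3418 in salt, 507 for the difference and 77 between the lines. Fitting only the compared groups, which leaves fewer samples, gave 749 for salt in line 1, 1536 for line 1 in control, 2004, 3331 and 1573 for line 1, line 2 and both in salt, and 78 between the lines. With a mean FPKM of at least 5, where fewer genes were tested, lines 1 and 2 in salt gave 2151 and 3327, both lines in control 1170 and line 2 against line 1 81. The library set as a term gave 3076 for salt in line 2 and 250 between the lines, and the cause was not tested. The set was drawn from the deviations of these same data, so the term takes out within-group spread by construction and is no independent check.

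Leaving out each library of the compared groups gave ranges of 2612 to 2959 for salt in WT, 1072 to 1545 in line 1, 696 to 1398 in line 2, 1416 to 2283 and 1685 to 2382 for lines 1 and 2 in control, 2295 to 3076 and 3965 to 4866 in salt, 1140 to 1744 and 1886 to 2632 for both lines in control and salt, 1202 to 1735 for the difference and 74 to 156 between the lines. Where a group kept 2 libraries the spread was shared with the other groups. Scaling to the gene total moved the share of higher calls from 48.6% to 38.8% for salt in line 1, from 48.9% to 23.7% for salt in line 2, from 57.4% to 73.9% for line 2 in control and from 42.4% to 61.9% between the lines. Of 9155 checks on 185 genes the rule named, 8865 kept their direction and side of the threshold. The preset set calls kept were 7 of 8 for salt in WT with the library set as a term and 7 of 8 for both lines in control when scaled to the gene total.

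The gene LotjaGi3g1v0486500, described as MYB36 and never past the threshold, changed sign in some settings. For LotjaGi3g1v0486500, salt effect in WT, the values were -0.15 under array weights, -0.0062 under voom on the recovered reads, -0.18 in the 10 libraries of the lower set, and from -0.0798 to 0.18 on leaving out each library of the compared groups (-0.0585 without WT salt replicate 1). For LotjaGi3g1v0486500, difference in salt effect between the lines and WT, the value was 0.0827 under array weights.

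With the replicate number as a block the count was 3257 for the salt effect in WT, 1667 for the salt effect in myb36 line 1 and 1662 for the salt effect in myb36 line 2. It was 2334 for line 1 against WT in control, 2521 for line 2 against WT in control, 3212 for line 1 against WT in salt and 5044 for line 2 against WT in salt. It was 1732 for both lines against WT in control and 2583 for both lines against WT in salt. It was 1613 for the difference in salt effect between the lines and WT and 142 for line 2 against line 1, and the set calls numbered 8, 8, 11 and 8 as without the block. The labels do not say that numbers pair samples. Deviations of same-numbered libraries correlated at a mean of 0.004, against 0.0018 for different numbers, 14 of 45 pairs lay above 0.1, and 7 of 18 libraries correlated best with their own number.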

Other observations

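The clustering of the genes near 0 was planned before its result, and the tests of 1 single segment, of separate events and of the iron genes were chosen after the result was seen. Genes of iron handling were looked at because ferritin-3 LotjaGi3g1v0197600 was high in both lines in control and low with salt. Of 3 ferritin genes 1 was higher in both lines in control, and ferritin-3 LotjaGi6g1v0079000 had 144 FPKM in WT control and 141 and 135 in the lines. Ferritin-2 LotjaGi1g1v0074300 had 55.4 FPKM in WT control and 67.7 and 65.4 in the lines, not past the threshold. With salt it fell in both lines (log2 change -0.61 in each, limma adjusted p = 4.99e-04 and 0.0013). Of 11 measured genes of iron uptake and deficiency 0 were higher and 1 was lower in both lines in control. That gene, oligopeptide transporter 3 LotjaGi4g1v0006400, known from Arabidopsis for iron movement in the phloem, had 37.4 ± 4.10 FPKM in WT control and 28.3 ± 0.725 and 27.6 ± 0.364 in the lines (SD, n = 3), lower in both by limma (adjusted p = 0.011 and 0.0050), and in salt it rose to 47.6 ± 0.961 and 47.1 ± 2.72 in the lines. A candidate explanation is iron excess in shoots of the lines in control, which would raise vacuolar iron transporter genes, and 1 of the 5 measured was higher in both lines, LotjaGi6g1v0356300 with 0.535 FPKM in WT control against 4.49 and 5.72. That count is too small to decide, and no iron content was used here.

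Some genes were read in 1 genotype and near 0 in the other. With FPKM of at least 1 in every library of a genotype and at most 0.1 in every library of the other, thresholds set after seeing the data, 2 were read in WT and near 0 in both lines, and 5 were read in both lines and near 0 in WT. Among the 5 were a lipase gene LotjaGi3g1v0397600, PMT16 methyltransferase LotjaGi2g1v0147400, 2 genes described as transposon polyproteins, LotjaGi1g1v0384600_LC and LotjaGi2g1v0357500_LC, and an assembled transcript, and in 1 line alone 4 further genes differed in this way.

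This pattern might come from a shared segment of another background around the mutation. The 7 genes lay on 4 chromosomes, which argues against 1 single segment shared by the lines. Clustering within 1 Mb gave a permutation p = 1 for a shared segment of another background, with 0 of 7 genes near another. The median of 10000 random draws was also 0, so 7 genes are too few to tell scattered differences apart. The lipase gene LotjaGi3g1v0397700, next in number to LotjaGi3g1v0397600, was also far higher in both lines in control. Its WT control mean lay above the limit of 0.1 FPKM, so the count near another depends on thresholds set after seeing the data. Reads shared between these 2 genes were not tested. Separate events in each line stay open for the 4 genes that differed in 1 line alone. The 1 gene near 0 in line 1 alone (start 39637619) lay on chromosome 3. The 2 assembled transcripts read in line 1 alone (starts 55167315 and 62059063) lay on that chromosome too. The 1 gene read in line 2 alone lay on chromosome 2. Clustering of these 4 was not tested.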
